A study of Rattus norvegicus with 18 samples.

How the data were processed

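Expression was measured on Affymetrix rat arrays in 18 samples: freshly isolated liver sinusoidal endothelial cells (5 arrays), the same cell type after 2 h (4 arrays) and 42 h (4 arrays) of culture, and freshly isolated lung microvascular endothelial cells (5 arrays). The deposited values are log2 expression per probe set, made by the authors from biotin-labelled cRNA. Their background correction, normalization and summarisation are not given in the sources used here. The unit was read from the values, which ran from 5.11 to 13.69 with array medians between 7.095 and 7.19, so they were tested as deposited, with no pseudocount. Probe sets are named by Entrez gene identifier. Of 11484 probe sets, 57 were array controls and 11427 gene probe sets; the 11018 with 1 gene symbol were tested, none had several, and 409 without a symbol were left out. Each gene had a single probe set. Array data have no counts, so the number of arrays sets the precision.

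The labels gave the 4 groups. No replicate number is shared between groups, so nothing was paired, and the labels do not state which animals the arrays came from. The 4 comparisons were LMEC_0h against LSEC_0h, LSEC_2h against LSEC_0h, LSEC_42h against LSEC_0h, and LSEC_42h against LSEC_2h. All 18 arrays entered a single linear model in limma 3.58.1 (R 4.3.3) with 1 mean per group and an intensity trend in the prior variance. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Folds come from the fitted log2 differences.

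The tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. For each comparison the named genes were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher mean lay above the median of all probe sets (7.15). Up to 4 called members of each list, some but not all members opposing their list, and a fixed set of endothelial genes were also named. Some genes of that set were not analysed here.

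Shifts of 28 gene lists in each of the 4 comparisons, 112 tests, were tested with camera at a preset correlation of 0.01. The same lists were tested with camera at an estimated correlation and with fry, each adjusted over all 112. Of the 43 calls with the preset correlation none held with an estimated correlation, whose smallest adjusted p was 0.057, and fry, which does not compare a list with other genes, called 72. Member counts are therefore given with every list. Adjusted over the list alone, the count of called members differed from that over all genes in 28 of the 112, by at most 3 members.

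Genes at least 2-fold apart between the organs were followed through culture as overlap counts. The main counts stand beside the counts for independent lists, and where LSEC_0h serves in both comparisons beside the 20 ways of dividing its arrays. The correlation and covariance of the log2 differences stand beside 100 simulations of unchanged groups. RNA quality was taken as the 3′ minus 5′ difference of the Actb and Gapdh control probe sets, tested by 8 exact permutation tests. The procedure was tested on simulated data with 200 changed genes: over the mean of 10 simulations, 93.1% to 97.3% of the 2-fold changes were recovered and 3.7% to 5.5% of the calls were false. A single simulation had been run first and gave more false calls in 1 comparison, after which 10 were averaged. The simulated values were drawn independently for each gene. In the data 47.5% to 74% of the genes were called, so these rates need not hold there.

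Alternatives were quantile normalization, a filter keeping 6803 genes above the array median in at least 4 arrays, only the 2 groups compared in the fit, no trend, array weights, all 11427 probe sets, a test against a 1.5-fold change, no 2-fold minimum, other list tests, and leaving out each array. Leaving out LMEC_0h arrays 19 and 22, leaving out LSEC_2h array 6 with LMEC_0h array 20 and LSEC_0h array 15, leaving out all LSEC_2h arrays, and leaving out marker list members were chosen after the values per array were seen. For RNA quality, the Actb difference between LSEC_42h and LSEC_0h was picked as the measure followed under the alternatives after the values were seen. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.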

Results

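Transcript levels were measured on Affymetrix rat arrays in 18 samples of endothelial cells. Liver sinusoidal endothelial cells (LSEC) line the fenestrated capillaries of the liver, and lung microvascular endothelial cells (LMEC) line continuous capillaries. Fresh cells, taken after isolation and magnetic sorting with no culture, gave 5 LSEC arrays (LSEC_0h) and 5 LMEC arrays (LMEC_0h). LSEC plated on collagen gave 4 arrays after 2 h (LSEC_2h) and 4 arrays after 42 h (LSEC_42h). No label says that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Values are log2 expression per gene for 11018 genes, and array medians lay between 7.095 and 7.19. The number of arrays limits the precision of every value.

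The first 3 principal components held 37.1%, 29.0% and 21.8% of the variance. The 2 h arrays had a narrower distribution than the others: their 75th percentiles lay between 7.999 and 8.079, against 8.184 to 8.309 in the other 3 groups. Bacterial poly-A control transcripts, which the Affymetrix protocol adds to the RNA before labelling, averaged 7.62 to 8.37 over 24 probe sets in the 2 h arrays and 7.68 to 7.86 in the 42 h arrays. The same probe sets averaged 5.72 to 5.74 in LSEC_0h and 5.66 to 5.68 in LMEC_0h, where single probe sets had group means of 5.48 to 6.26 and 5.41 to 6.21. A gene whose lower group mean lies in these ranges is not above background there, so its fold is a lower bound. Of the genes named here that holds for Tspan8, Sftpa1, Sftpc, Olr1, Mfap4, Wif1, Tmem100, Scn7a, Selp, Klrd1, Lcn2 and Nr4a3 in LSEC_0h, for Alb, Clec4m, Gata4, Tfec and Ttr in LMEC_0h, and, by the LSEC_0h range, for Ackr4, Cyp26a1, Fos and Gzma at 42 h. The highest value of an array was 13.48 to 13.69. Among the genes named here, means above 13, close to these, were those of Dnase1l3, Fcgr2b and Ctsl in LSEC_0h, Sftpc in LMEC_0h, Cxcl1, Cxcl2, Cxcl10, Ctsl and Egr1 at 2 h, and Akr1b8, Fabp4, Fcgr2b and Ctsl at 42 h, and their folds may be understated, which was not tested. Every cultured array therefore carried these controls and no fresh array did, so the comparisons of cultured with fresh LSEC do not by themselves separate culture from labelling. The organ comparison and the comparison of 42 h with 2 h each lie within 1 kind. The difference between the 3′ and 5′ probe sets of Actb, a sign of RNA quality, was 1.85 ± 0.03 (SD, n = 4) at 42 h, 1.65 ± 0.03 (SD, n = 4) at 2 h, 1.02 ± 0.15 (SD, n = 5) in LSEC_0h and 1.05 ± 0.16 (SD, n = 5) in LMEC_0h. Two-sided exact permutation tests of the 2 h and of the 42 h arrays against LSEC_0h each gave p = 0.0159, the smallest these group sizes allow, and 0.0635 after Benjamini-Hochberg adjustment over 8 tests, so neither difference passed. The values did not overlap, with 1.63 to 1.69 at 2 h and 1.81 to 1.89 at 42 h against 0.91 to 1.28 in LSEC_0h. With p at its smallest, the failure to pass does not show that RNA quality was alike. The 42 h arrays lay 0.2 above the 2 h arrays (exact permutation p = 0.0286, the smallest for 4 against 4, and 0.0762 adjusted), which did not pass either. The same difference for Gapdh lay between 0.34 and 0.46 in the means of all 4 groups (exact permutation p between 0.73 and 1 in the 4 comparisons).

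The comparison of fresh cells asked which transcripts set liver sinusoidal endothelium apart from lung microvascular endothelium. Dnase1l3 (Entrez gene 116687), a secreted nuclease, gave 13.25 ± 0.06 (SD, n = 5) in LSEC_0h and 6.47 ± 0.12 (SD, n = 5) in LMEC_0h, a 110-fold difference (log2 SE 0.23, limma adjusted p = 8e-14), taken like that of Fcgr2b close to the highest values of the arrays. Fcgr2b (Entrez gene 289211), an inhibitory Fc receptor that takes up immune complexes, was 43.9-fold higher in LSEC_0h at 13.31 ± 0.05 against 7.86 ± 1.0 (SD, n = 5 each, limma adjusted p = 1.27e-10). Ehd3, which acts in endosome recycling, was 34.8-fold higher, the C-type lectin Clec4m 24.5-fold, the phosphodiesterase Pde2a 20.3-fold, the transporter Abca8a 19.6-fold, the chemokine Ccl24 15.5-fold and Cyp26a1, which breaks down retinoic acid, 15.5-fold. Of the 11018 genes, 5235 differed at an adjusted p under 0.05, 2182 higher and 3053 lower in LMEC_0h, and 650 and 438 of these differed at least 2-fold. The 2 groups did not overlap in 38.7% of all genes, where chance gives 0.79%.

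Transcription factors and secreted factors of LSEC were lower in the lung cells in 13 of 15 measured members. Bmp2 (Entrez gene 29373), a secreted growth factor that regulates iron uptake, was 14-fold higher in LSEC_0h, Gata4 11.5-fold, Maf 10.8-fold and Tfec 9.26-fold, the last 3 being transcription factors. Pianp (Entrez gene 312711), which encodes the junctional protein named in the study's title, was 8.47-fold higher at 9.83 ± 0.37 against 6.75 ± 0.05 (SD, n = 5 each), and Wnt2 was 7.76-fold higher. Il6r went the other way, 2.73-fold higher in LMEC_0h. Pianp and other members are known from the study itself, so the direction of this list is not independent evidence, here or in the culture comparisons below. The list test gave an adjusted p of 1.3e-07, and adjusted p = 0.23 with an estimated correlation. Scavenger and endocytic receptors were lower in LMEC_0h in 7 of 10 members, with Dab2 6.73-fold and the hyaluronan receptor Lyve1 2.79-fold higher in LSEC_0h, while Cd14 and Scarb1 were higher in LMEC_0h. That call (adjusted p = 0.047) had adjusted p = 0.56 with an estimated correlation and was lost without any 1 of 6 arrays (adjusted p 0.051 to 0.08) and with dim genes left out (adjusted p = 0.099). Stab1, Stab2, Cldn5 and Pecam1 were not analysed here. Lysosomal genes were lower in LMEC_0h in 18 of 25 members, among them Hexa, Tpp1, Ctss and Ctsl, and 2 were higher (list adjusted p = 0.00079, adjusted p = 0.57 with an estimated correlation). Over the LSEC_0h arrays the lysosomal and macrophage marker means ranked alike, from 10.26 and 10.09 in array 15 to 10 and 7.78 in array 17, and Ctss ran from 11.5 to 8.77. With the hepatocyte and macrophage marker means as covariates, a test chosen after these values were seen, 9 of the 18 were still lower, and their median log2 difference went from -0.65 (median SE 0.12) to -0.58 (median SE 0.22).

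In the other direction, genes of lung and continuous endothelium were higher in LMEC_0h in 25 of 32 members. Tmem100 was 76.8-fold higher, the clotting factor carrier Vwf 51.0-fold (12.42 ± 0.26 against 6.75 ± 0.18, SD, n = 5 each), the sodium channel Scn7a 44.8-fold and Ace, the angiotensin-converting enzyme, 39.9-fold. Nos3, endothelial nitric oxide synthase, opposed its list and was 5.26-fold higher in LSEC_0h. This list had an adjusted p of 1.5e-17, and adjusted p = 0.057 with an estimated correlation. Caveolar genes were higher in 5 of 8 members, with Cav1 15.9-fold and Ehd2 11.8-fold (list adjusted p = 0.00046, adjusted p = 0.56 with an estimated correlation). Actin cytoskeleton genes were higher in 17 of 33 members and lower in 5 (adjusted p = 0.0028, adjusted p = 0.56 with an estimated correlation), and extracellular matrix and proteolysis genes were higher in 19 and lower in 7 (adjusted p = 0.00068, adjusted p = 0.57 with an estimated correlation). Of 24 pan-endothelial genes, 3 were higher and 9 lower. Cdh5, the adherens junction cadherin of all endothelium, gave 11.93 ± 0.17 in LMEC_0h and 11.68 ± 0.07 in LSEC_0h (SD, n = 5 each), which did not pass (limma adjusted p = 0.109) but did with only these 2 groups in the fit (limma adjusted p = 0.024).

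Markers of other cell types differed by organ as well. Tspan8, Mfap4 and Wif1 were among the 10 genes furthest above LSEC_0h, Tspan8 at 79.6-fold or more, since its 5.74 in LSEC_0h was at the level of the absent controls. The surfactant genes Sftpc and Sftpa1 were at least 128-fold and 55.0-fold higher in LMEC_0h, where Sftpc reached 13.2 ± 0.26 (SD, n = 5), and 13 of 15 lung epithelial markers were higher (list adjusted p = 3.2e-12, adjusted p = 0.44 with an estimated correlation). Stellate cell and mesenchymal markers were higher in 15 of 20 members, led by Mgp at 49.7-fold and by the collagens Col1a2, Col1a1 and Col3a1 (adjusted p = 1.7e-05, adjusted p = 0.56 with an estimated correlation). Hepatocyte markers were lower in LMEC_0h in 23 of 26 members, Alb 76.5-fold, Ttr 10.8-fold and Ahsg 8.35-fold (adjusted p = 3.7e-05, adjusted p = 0.73 with an estimated correlation). Macrophage and Kupffer cell markers were lower in 8 of 13 members, Clec4f 17.2-fold and C1qa 8.65-fold, and 1 member, Laptm5, was higher (adjusted p = 0.036, adjusted p = 0.77 with an estimated correlation); this call was lost without LMEC_0h array 18, 19 or 21. T, NK and B cell markers were higher in LMEC_0h in 10 of 19 members and lower in 2 (adjusted p = 0.0095, adjusted p = 0.73 with an estimated correlation, and 0.096 with dim genes left out), and their mean was 7.72 in array 22 against 6.6 to 7.12 in the other LMEC_0h arrays. Cholangiocyte and other epithelial markers were higher in 6 of 8 (adjusted p = 0.00047, adjusted p = 0.57 with an estimated correlation). The mean of the hepatocyte markers ranged from 7.75 to 9.23 over the LSEC_0h arrays and from 6.46 to 6.53 over the LMEC_0h arrays, and that of the lung epithelial markers from 6.72 to 6.79 and from 9.55 to 11.15.

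Immediate early genes, which respond within minutes to stimulation, were higher in fresh LMEC in 23 of 27 members, with Atf3 7.58-fold, Gadd45b 5.02-fold, Myc 4.78-fold and Nr4a1 4.61-fold (list adjusted p = 1.9e-11, adjusted p = 0.09 with an estimated correlation). NF-kB and inflammatory genes were higher in 19 of 28 members (adjusted p = 3e-06, adjusted p = 0.57 with an estimated correlation). The mean of the latter list was 9.76 and 9.95 in LMEC_0h arrays 19 and 22, 8.43 to 9.19 in the other 3 LMEC_0h arrays, and 7.78 to 8.13 in LSEC_0h. Without arrays 19 and 22, 24 immediate early genes and 18 NF-kB genes were higher in LMEC_0h, and 5 NF-kB genes were lower against 1 with all arrays.

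**Figure D1:**
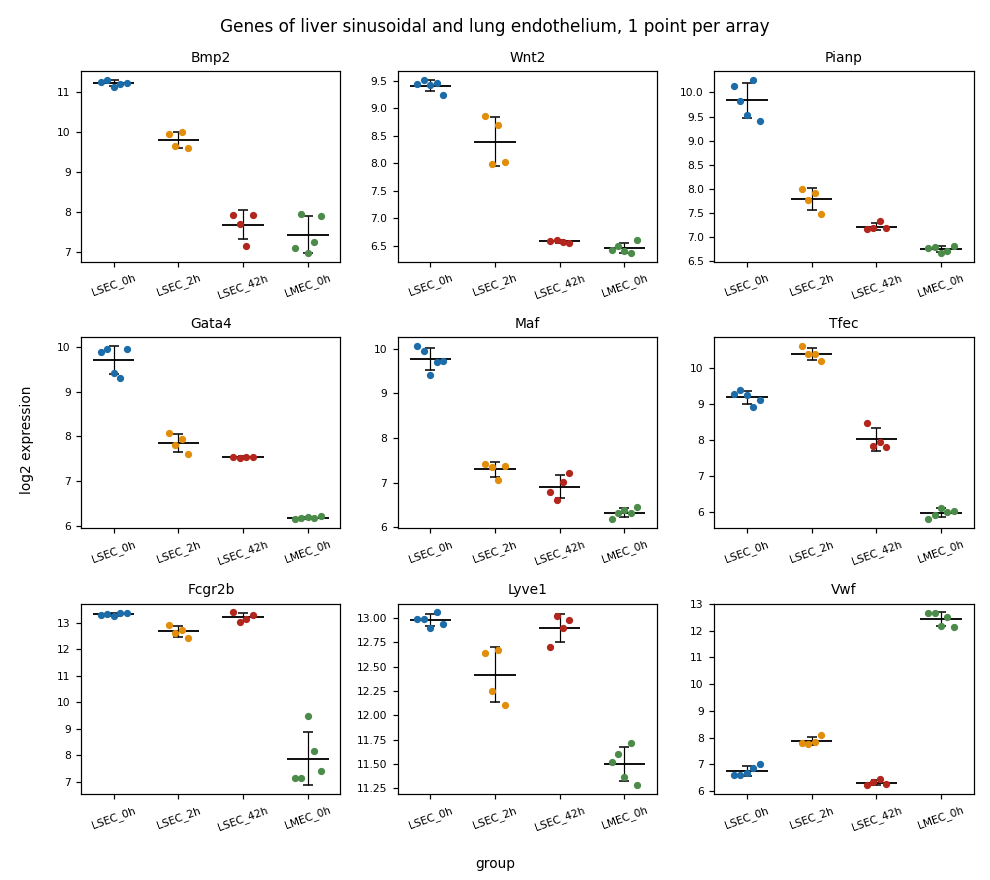
Log2 expression (vertical axis) of 9 genes in each of the 18 arrays, as points by group (horizontal axis), with the group mean as a bar and 1 SD as the error bar. Bmp2, Wnt2, Pianp, Gata4 and Maf were near the LMEC_0h level or part of the way to it at 42 h, while Fcgr2b and Lyve1 at 42 h (means 13.22 and 12.9) lay near their LSEC_0h means (13.31 and 12.98).

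The comparison of 2 h in culture with fresh LSEC covered the earlier time. Chemokine genes were among those that rose most: Cxcl11 (Entrez gene 305236) went from 6.86 ± 0.23 (SD, n = 5) to 12.91 ± 0.17 (SD, n = 4), a 66.2-fold rise (log2 SE 0.17, limma adjusted p = 1.3e-13), Cxcl2 rose 49.7-fold, Cxcl10 17.5-fold and Cxcl1 16.3-fold. Akr1b8, an aldo-keto reductase, rose 30.4-fold, the oxidised LDL receptor Olr1 at least 26.1-fold (from 5.55, background level), the sphingosine kinase Sphk1 21.7-fold, the deadenylase Noct 21.2-fold, Tiparp 16.7-fold and the quinone reductase Nqo1 16.2-fold. NF-kB and inflammatory genes rose in 23 of 28 members and none fell (list adjusted p = 4.6e-05, adjusted p = 0.57 with an estimated correlation). Immediate early genes rose in 22 of 27, among them Myc 12.6-fold, Nr4a3 6.7-fold, Klf6 5.21-fold and Gadd45b 4.57-fold, while Klf2 and Jund fell (adjusted p = 0.0004, adjusted p = 0.57 with an estimated correlation). Genes of the oxidative stress response to the factor NRF2 rose in 9 of 13, led by Nqo1, Sod2, Gclc and Txnrd1, although the list itself was not called (adjusted p = 0.066; 0.03 without LSEC_2h array 4, 0.049 without LSEC_0h array 15 and 0.004 with dim genes left out). In all, 8158 genes changed, 4558 up and 3600 down, 627 and 800 of them at least 2-fold. With genes kept only where they lay above the array median in at least 4 arrays, 5108 of 6803 changed and 36.1% of these rose, against 55.9% of all the genes called.

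Within the same 2 h Sox18, an endothelial transcription factor, fell 8.22-fold, Tmem204 9.24-fold, Ehd3 7.3-fold and Cyp26a1 7.92-fold; the phosphatase gene Sgpp1 fell 8.28-fold and Eva1b 7.41-fold. Of 24 pan-endothelial genes 16 fell and 4 rose, with Sox18, Mmrn2, Nos3 and Shank3 falling most and S1pr1 and Fli1 rising (adjusted p = 0.0064, adjusted p = 0.57 with an estimated correlation). That call was lost with dim genes left out (adjusted p = 0.2). Of 15 LSEC transcription and secreted factors, 9 fell and 3 rose (adjusted p = 0.025, adjusted p = 0.57 with an estimated correlation, and 0.3 with dim genes left out). Maf fell 5.53-fold, Pianp 4.12-fold, Gata4 3.59-fold, Bmp2 2.7-fold and Wnt2 2.03-fold, while Tfec rose 2.3-fold. Junction genes fell in 11 of 20 members, Cdh5 2.44-fold among them (adjusted p = 0.027, adjusted p = 0.57 with an estimated correlation, and 0.17 with dim genes left out), and lysosomal genes in 19 of 25 (adjusted p = 0.0004, adjusted p = 0.57 with an estimated correlation), 16 of them also with the marker means as covariates. Actin cytoskeleton genes fell in 14 of 33 and rose in 5 (adjusted p = 0.046, adjusted p = 0.57 with an estimated correlation), a call lost without any 1 of 8 arrays (adjusted p 0.05 to 0.067) and with dim genes left out (adjusted p = 0.61). Lyve1 fell 1.47-fold. Fcgr2b did not pass at 12.67 ± 0.20 (SD, n = 4) against 13.31 ± 0.05 (SD, n = 5; limma adjusted p = 0.092), though it passed with only these 2 groups in the fit (limma adjusted p = 6.72e-05). Vwf rose 2.16-fold, and Cav1 fell 1.56-fold, a call lost without any 1 of 7 arrays (limma adjusted p 0.0516 to 0.108).

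Other cell types also differed between these arrays. Macrophage and Kupffer cell markers fell in 8 of 13 members at 2 h, with C1qa at 9.05-fold, C1qc at 8.83-fold and Clec4f at 8.47-fold (adjusted p = 0.046, adjusted p = 0.77 with an estimated correlation); the list's call was lost without any 1 of 7 arrays (adjusted p 0.05 to 0.058) and with dim genes left out (adjusted p = 0.14). The chemokine Ccl6 fell 9.92-fold. Hepatocyte markers fell in 3 of 26 members, but their mean was 9.81 in LSEC_2h array 6 against 6.8 to 7.45 in the other 3, and without that array together with LSEC_0h array 15 and LMEC_0h array 20, 19 of 26 fell. The list was not called with all arrays (adjusted p = 0.16) but was without array 6 alone (adjusted p = 9.8e-05). Adjusted over the list alone, none of the 26 passed. Of 19 T, NK and B cell markers 10 rose, led by the cytotoxic cell genes Gzma at 15.7-fold, Cd7 at 5.98-fold, Prf1 at 5.67-fold and Klrd1 at 3.76-fold, and Lck fell (adjusted p = 0.025, adjusted p = 0.77 with an estimated correlation). Stellate cell and mesenchymal markers rose in 15 of 20 members, 2 of them at least 2-fold (adjusted p = 0.042, adjusted p = 0.71 with an estimated correlation). That call was lost without any 1 of 3 arrays (adjusted p 0.05 to 0.086). Mgp rose 3.09-fold, with 9.38 in LSEC_2h array 6 against 7.58 to 7.89 in the other arrays. The list mean was 6.52 to 6.84 in LSEC_0h, below the median of all probe sets (7.15). Dim genes often rose at 2 h: 4558 of 11018 genes rose, against 1846 of 6803 with dim genes left out. The count of 15 is therefore not a result about these cells.

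The comparison of 42 h with fresh LSEC covered the later time. Bmp2 fell from 11.23 ± 0.07 (SD, n = 5) to 7.67 ± 0.36 (SD, n = 4), an 11.8-fold fall (log2 SE 0.20, limma adjusted p = 2.73e-10), Maf fell 7.26-fold, Wnt2 7.15-fold and Pianp 6.13-fold, the last to 7.22 ± 0.08 (SD, n = 4). Adamts1, a secreted protease, fell 8.9-fold, Gata4 4.49-fold and Tfec 2.25-fold. Of the 15 LSEC transcription and secreted factors 14 fell and none rose (list adjusted p = 2.9e-11, adjusted p = 0.09 with an estimated correlation). As between the organs, this direction is not independent evidence. Among the scavenger receptors, Fcgr2b was 13.22 ± 0.16 and Lyve1 12.9 ± 0.14 (SD, n = 4 each), neither of which differed from LSEC_0h (limma adjusted p = 0.834 and 0.616), and of the 10 members 3 fell, namely Ehd3 6.84-fold, Lrp1 2.53-fold and Dab2 2.02-fold, while Scarb2 rose 1.83-fold. Over the LSEC_0h arrays Lrp1 and the macrophage marker mean ranked alike, from 9.04 and 10.09 in array 15 to 7.34 and 7.78 in array 17. Whether the fall of Lrp1 came from the LSEC was not tested. Fcgr2b lay close to the highest values of the arrays (13.48 to 13.69), which limits what its values can show. The list was not called (adjusted p = 0.2), and the shifts of the 2 lists were not compared with each other. The chemokine scavenging receptor Ackr4 fell 30.4-fold, Cyp26a1 20.3-fold, Ccl24 16.8-fold and Ccdc80 14.9-fold.

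The genes that rose most by 42 h were Akr1b8 at 55.7-fold, the fatty acid carrier Fabp4 at 41.3-fold, Esm1, an endothelial proteoglycan of sprouting vessels, at 24.6-fold, Mmd at 19.1-fold, Ccn2 at 14.2-fold, Ugp2 at 10.1-fold, Myc at 10-fold, Sod2 at 9.92-fold and the asparagine synthetase Asns at 9.79-fold. Lcn2 rose 14.5-fold, with a spread of 2.11 (SD, n = 4) on the log2 scale at 42 h, and its log2 difference of 3.86 was 3.1 without LSEC_42h array 1 and 4.59 without array 2. Sterol synthesis genes rose in 13 of 14 members, led by Idi1 4.87-fold, Sqle 3.19-fold, Msmo1 3.01-fold and Cyp51 2.95-fold (list adjusted p = 0.00046, adjusted p = 0.57 with an estimated correlation). Of 21 sprouting genes 7 rose, among them Esm1, Cxcr4 9.66-fold and Apln 7.03-fold, and 8 fell, among them Flt1 4.6-fold, and the list was not called (adjusted p = 0.38). Cxcr4 had a spread of 1.5 (SD, n = 4) on the log2 scale at 42 h, and its log2 difference of 3.27 was 2.64 without LSEC_42h array 12. Cell cycle genes rose in 13 of 25 members, with Mcm7 at 4.63-fold, and Ccnd1 fell (adjusted p = 0.025, adjusted p = 0.8 with an estimated correlation); the call was lost without LSEC_42h array 2 (adjusted p = 0.16) and with dim genes left out (adjusted p = 0.073). Over all genes 5570 changed, 3276 up and 2294 down, 454 and 594 of them at least 2-fold.

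Genes of continuous endothelium did not rise as a group by 42 h. Of 32 members 16 fell and 4 rose, with Gja4, Thbd, Ly6c and Calcrl falling 4.04-fold to 5.66-fold and Apln, Ace, Edn1 and Selp rising (adjusted p = 0.0042, adjusted p = 0.57 with an estimated correlation). Vwf fell 1.35-fold, and Cav1 was 8.0 ± 0.81 (SD, n = 4) against 7.4 ± 0.12 (SD, n = 5), which did not pass (limma adjusted p = 0.0769) but did without LSEC_42h array 1 or 12 (limma adjusted p = 0.042 and 0.00984). Of 24 pan-endothelial genes 15 fell and 3 rose (adjusted p = 0.00052, adjusted p = 0.57 with an estimated correlation). Junction genes fell in 12 of 20 members, with Jam2, Pianp, Gja4 and Jup falling most (adjusted p = 0.002, adjusted p = 0.56 with an estimated correlation). Cdh5 fell 1.3-fold, a call lost without LSEC_42h array 1 or 2 or LSEC_0h array 14 (limma adjusted p = 0.131, 0.0821 and 0.0548) and with only these 2 groups in the fit (limma adjusted p = 0.058). Immediate early genes fell in 17 of 27 members below the level of fresh LSEC, with Fos at least 46.8-fold and Egr1 14.3-fold lower, while Myc, Ccn2 and Klf6 rose (adjusted p = 1e-08, adjusted p = 0.19 with an estimated correlation). The heat shock gene Hspa1b fell 26.6-fold. Antigen presentation genes fell in 10 of 18 members and none rose, the invariant chain gene Cd74 by 9.78-fold and the class II genes RT1-Da and RT1-Ba by 5.3-fold and 5.17-fold (adjusted p = 0.00079, adjusted p = 0.57 with an estimated correlation). In LSEC_0h, Cd74, RT1-Da and the mean of the macrophage markers were all highest in array 15 (12.03, 11.97 and 10.09) and lowest in array 17 (8.7, 8.28 and 7.78). With the hepatocyte and macrophage marker means as covariates, a test chosen after these values were seen, none of the 10 antigen presentation genes still fell, and their median log2 difference went from -1.33 (median SE 0.3) to 0.2 (median SE 0.35). Lysosomal genes fell in 17 of 25 (adjusted p = 0.00015, adjusted p = 0.57 with an estimated correlation), and with the same covariates 5 of the 17 still fell, their median going from -0.82 (median SE 0.15) to -0.59 (median SE 0.27).

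Marker genes of other liver cells fell over the same 42 h. All 26 hepatocyte markers fell, Alb 51.8-fold (adjusted p = 9.7e-09, adjusted p = 0.57 with an estimated correlation), and 10 of 13 macrophage and Kupffer cell markers fell, Clec4f 15.5-fold and C1qa 13.2-fold (adjusted p = 3.3e-05, adjusted p = 0.57 with an estimated correlation). Ccl6 fell 20.4-fold. The mean of the hepatocyte markers was 6.22 to 6.33 in the 42 h arrays, against 7.75 to 9.23 in LSEC_0h, and that of the macrophage markers was 6.5 to 6.82, against 7.78 to 10.09. None of the stellate cell and mesenchymal markers rose and 3 of 20 fell, 17 not passing.

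**Figure D2:**
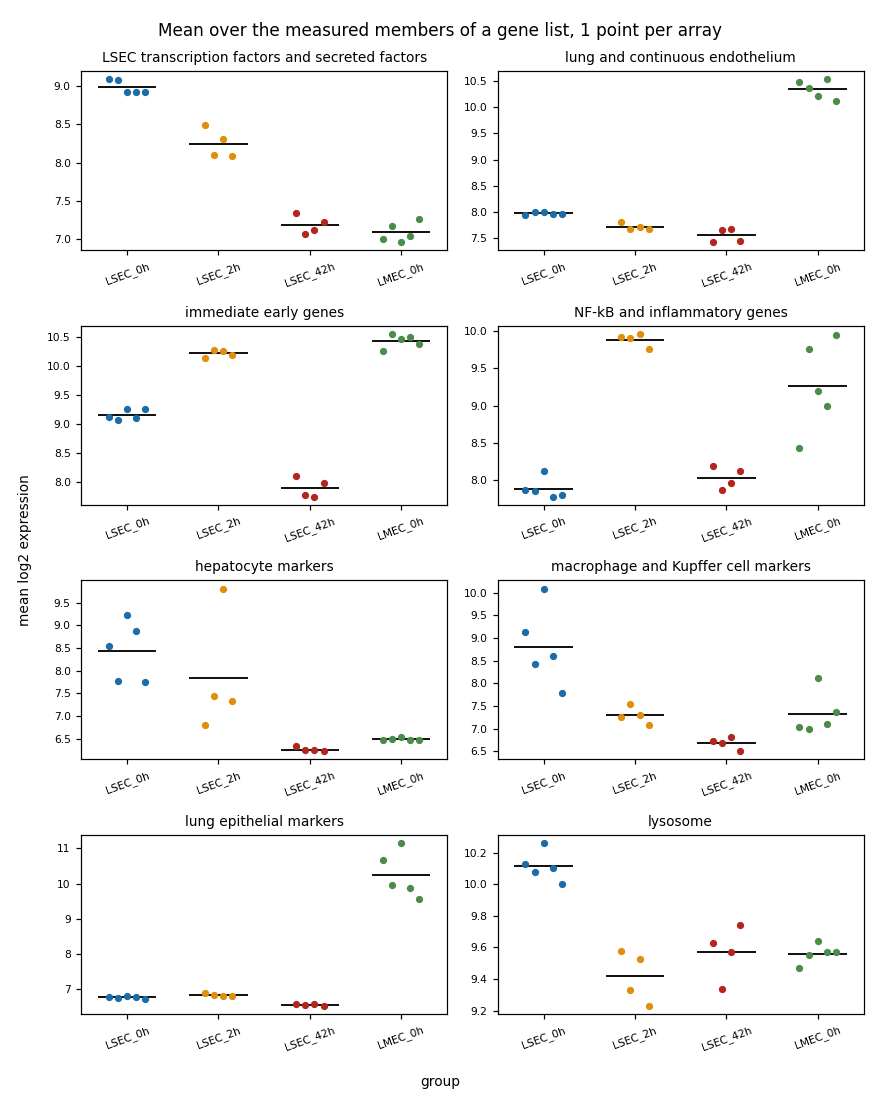
Mean log2 expression over the measured members of 8 gene lists (vertical axis) in each of the 18 arrays, as points by group (horizontal axis), with the group mean as a bar. The immediate early gene mean was 10.14 to 10.28 at 2 h and 7.74 to 8.1 at 42 h, and the hepatocyte marker mean of LSEC_2h array 6 stood at 9.81.

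Between 2 h and 42 h, within arrays that all carried the poly-A controls, the early response receded. The arrays of these times also differed in their hybridisation controls, as given below. Cxcl11 fell 90.1-fold, from 12.91 ± 0.17 to 6.42 ± 0.06 (SD, n = 4 each, log2 SE 0.18, limma adjusted p = 4.77e-14), Cxcl10 65.7-fold and Cxcl9 32.2-fold. The interferon-induced genes Rsad2, Isg15 and Ifit1 fell 26.4-fold, 24.4-fold and 22.4-fold. Immediate early genes fell in 25 of 27 members, Fos at least 55.1-fold, Egr1 48.9-fold and Gadd45g 27.3-fold, and Ccn2 alone rose, 6.12-fold (list adjusted p = 2.2e-11, adjusted p = 0.09 with an estimated correlation). NF-kB and inflammatory genes fell in 21 of 28 and none rose (adjusted p = 5.3e-05, adjusted p = 0.57 with an estimated correlation). Antigen presentation genes fell in 11 of 18 and none rose (adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation). Hspa1b fell 23.2-fold. T, NK and B cell markers fell in 13 of 19, Gzma 20.4-fold (adjusted p = 0.00068, adjusted p = 0.57 with an estimated correlation). Hepatocyte markers fell in 24 of 26 (adjusted p = 0.0025, adjusted p = 0.78 with an estimated correlation). Their median log2 difference was -1.48, and -0.8 without LSEC_2h array 6. Stellate cell and mesenchymal markers fell in 15 of 20, Col3a1 8.69-fold among them (adjusted p = 0.0059, adjusted p = 0.57 with an estimated correlation), and 4 of the 15 fell at least 2-fold. Dim genes often fell in this step: 4290 of 11018 genes fell, against 1747 of 6803 with dim genes left out.

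LSEC transcription and secreted factors fell in this step in 13 of 15 members and none rose: Adamts1 fell 8.01-fold, Tfec 5.17-fold, Bmp2 4.38-fold, Wnt2 3.52-fold and Pianp 1.49-fold (adjusted p = 0.00079, adjusted p = 0.57 with an estimated correlation). Maf fell 1.31-fold and Gata4 1.25-fold; the call for Gata4 was lost without any 1 of 6 arrays (limma adjusted p 0.0546 to 0.115) and that for Maf without LSEC_42h array 2 (limma adjusted p = 0.0641). Of 24 pan-endothelial genes 8 rose and 6 fell (adjusted p = 0.69), and of 20 junction genes 7 rose and 6 fell (adjusted p = 0.95), neither list being called. Sox18 rose 8.08-fold, from 8.06 ± 0.18 to 11.07 ± 0.91 (SD, n = 4 each), beside 11.1 ± 0.13 (SD, n = 5) in LSEC_0h, Cdh5 rose 1.87-fold, Lyve1 1.39-fold and Cav1 2.35-fold, and Vwf fell 2.93-fold. Fcgr2b was 1.46-fold higher at 42 h and did not pass (limma adjusted p = 0.173), though it did with only these 2 groups in the fit (limma adjusted p = 0.00332). Apln rose 10.6-fold, Lcn2 9.41-fold, Gpx8 8.06-fold, Esm1 7.97-fold, Ugp2 7.26-fold, St3gal2 6.65-fold, Msmo1 6.45-fold and Nhp2 6.23-fold. The log2 difference of Lcn2, 3.23, was 2.48 without LSEC_42h array 1 and 3.96 without array 2. In all 7939 genes changed, 3649 up and 4290 down, 969 and 618 of them at least 2-fold, and with the filter on dim genes 4963 changed, 64.8% of them up against 46.0% of all the genes called. Of the genes called in both comparisons with LSEC_0h and in this one, 876 fell at 2 h and rose by 42 h and 234 rose at 2 h and fell by 42 h. Against LSEC_0h, 1523 genes rose at both times and 1460 fell at both.

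The genes that marked LSEC against LMEC were then followed through culture. Of the 438 genes at least 2-fold higher in LSEC_0h, Bmp2, Gata4, Maf and Pianp among them, 370 (84.5%) fell by 42 h and 13 rose. Independent lists of these sizes would share 91.2 genes. Both comparisons use LSEC_0h; with its 5 arrays divided between them in each of the 20 possible ways, the overlap was 303 to 366 (median 338.5), against a median of 77.1 for independent lists. Without the members of the marker lists of other cell types, 342 genes fell. By 2 h, 312 of the 438 had fallen, where independent lists would share 143.1, and 20 had risen. With the LSEC_0h arrays divided, the 312 became 279 to 326, against a median of 133.2 for independent lists, a division added after the result was seen. Brighter genes fell more often at 2 h, 3262 of 6803 with dim genes left out against 3600 of 11018. The same held at 42 h, with 1927 of 6803 against 2294 of 11018. The values for independent lists at both times are therefore too low for genes of this level, and the size of each excess is overstated. Between 2 h and 42 h, a comparison that shares no array with the organ comparison, 188 fell and 103 rose, where independent lists would share 170.5 and 145.1 (odds ratio across genes for falling 1.19 by Fisher's exact test). With quantile normalization 184 fell, while all falling genes went from 4290 to 3047 of 11018. With dim genes left out 186 fell, and 1747 of 6803 genes fell in all. The odds ratio was not computed there, and it depends on how many dim genes fall. Of the 650 genes at least 2-fold higher in LMEC_0h, 273 fell in this step and 75 rose, where independent lists would share 253.1 and 215.3. Of the 370 genes, 180 also fell between 2 h and 42 h. Across genes, which are not independent replicates, the log2 differences between organs and those at 42 h against LSEC_0h had r = 0.341 and a covariance of 0.162, against 0.473 and 0.00841 in the simulated unchanged groups, and 0.33 and 0.158 with the LSEC_0h arrays divided. For 42 h against 2 h the sign was the opposite, with r = -0.104 and a covariance of -0.0576, against 0.00139 and 2.66e-05 in the simulated unchanged groups.

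The opposite direction did not mirror this. Of the 650 genes at least 2-fold higher in LMEC_0h, Vwf, Cav1 and Tmem100 among them, 147 (22.6%) rose by 42 h in cultured LSEC and 105 fell. The 650 also held genes of other lung cells, such as Sftpc and Mgp, and 37 were members of the marker lists. Without the marker list members 147 rose as well, so none of these members was among the genes that rose. Whether all of the 147 are endothelial genes was not tested. Independent lists would share 193.3 genes, and with the LSEC_0h arrays divided the overlap was 112 to 141 against a median of 154.6. With only the groups compared in each fit, 224 rose. At 2 h, 331 of the 650 had risen and 51 had fallen, where independent lists would share 268.9 and 212.4, and with the LSEC_0h arrays divided 252 to 317 rose, against a median of 240.6.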

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

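Tests chosen after the result was seen were the division of the LSEC_0h arrays as a bound, the medians of the covariate fit, both tests on the poly-A controls with the division of the LSEC_2h arrays, and both tests on the lung arrays.

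Poly-A control transcripts, used in no comparison, averaged 8.06 in LSEC_2h and 7.8 in LSEC_42h, above the 5.73 and 5.67 of the fresh LSEC and LMEC. For some genes the effects of culture differed between 2 h and 42 h, while 1523 genes rose and 1460 fell at both: 12 immediate early genes rose at 2 h and fell by 42 h against LSEC_0h, each also falling in the comparison of 42 h with 2 h.

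Genes higher in LSEC than in LMEC fell by 42 h in 370 of 438 cases, more than in any other division run (highest 243). Those divisions called at most 3990 genes at 42 h against 5570, so they do not by themselves exclude chance for the overlap. For the 188 that fell between 2 h and 42 h (highest other 27) the divisions decide nothing, as they called at most 1270 genes against 7939, and independent lists would share 170.5. The LSEC_0h arrays used in both comparisons do not account for the 370, since the lowest overlap with these arrays divided was 303. With hepatocyte and macrophage marker means as covariates, the median of the hepatocyte markers went from -2.31 to 0.08, which the fit sets in advance. That of the 342 genes outside the marker lists went from -1.24 (median SE 0.16) to -1.07 (0.28). For the LSEC transcription and secreted factors that fell it went from -2.15 (0.14) to -2.51 (0.29). These genes were chosen because they fell, and the slopes come from the spread within groups. The hepatocyte means at 42 h (6.22 to 6.33) lay outside those of LSEC_0h (7.75 to 9.23), so the fit extrapolates. Only if the slopes hold there do the values argue against loss of those cells' RNA as the whole cause. Of the 342 genes 217 still fell, between the bounds set before, and 11 of 14 factors; for the other 125 the median went from -1.08 (0.24) to -0.41 (0.31), a smaller fold and a wider spread, so for these the loss stays open. Labelling and culture cannot be told apart, as every cultured array and no fresh array carried the controls. The Actb 3′ minus 5′ difference also separated cultured from fresh LSEC arrays, while that of Gapdh did not, so RNA quality stays open too. Within the cultured arrays 180 of the genes also fell, with an odds ratio of 1.19 for the set. That ratio decides nothing, since it rests on the 4290 genes that fell in all. After quantile normalization 3047 fell in all, and 184 of the set.

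At 2 h, 1427 genes changed at least 2-fold, and chance in the grouping of these arrays can be excluded for the 8158 changed genes (highest other division 6910). The narrower distribution of the 2 h arrays is not the whole cause, since 1426 changed the same way after quantile normalization, 1237 of them still 2-fold. A labelling effect equal in both cultured groups would hold at 42 h, but 1069 (74.9%) moved back between 2 h and 42 h. With 2 of the LSEC_2h arrays choosing the genes and the other 2 compared with 42 h, 62.4% to 75.6% moved back and 4.2% to 12% further, where no change would leave the 2 shares alike. The BioB hybridisation controls, however, were 8.69 to 8.78 in the 2 h arrays and 7.87 to 8.2 in the 42 h arrays. A technical effect shared by the 2 h arrays alone is therefore not excluded, and dividing these arrays cannot detect it. For the genes that did not move back labelling stays open, and no biological explanation was tested.

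Immediate early and NF-kB genes were higher in LMEC_0h in 42 of 55 cases. Without LMEC_0h arrays 19 and 22, 41 were still higher, with a median of 1.46 against 1.66, so these arrays alone are not the cause. The isolation of lung cells and the organ itself cannot be told apart, since every lung array had both: the 42 genes may reflect either.

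Of 644 groups of values tested for 1 array apart from the others, 36 (5.6%) had one, and chance gives about 1 in 20. The log2 values of those arrays follow, for list means, control differences and genes. LMEC_0h array 19 stood apart in Cxcr4 (8.99). LMEC_0h array 20 stood apart in neutrophil and monocyte markers (7.98), Adamts1 (9.86), C1qa (8.54) and C1qc (8.53). LMEC_0h array 21 stood apart in Col1a2 (9.23). LMEC_0h array 22 stood apart in the Actb 3′ minus 5′ difference (1.34), Cav1 (10.77) and Lck (8.75). LSEC_0h array 14 stood apart in Gadd45b (8.94). LSEC_0h array 15 stood apart in NF-kB and inflammatory genes (8.13), Sgpp1 (10.05) and Sod2 (9.53). LSEC_0h array 16 stood apart in caveolae (8.65), unfolded protein and amino acid response (9.32), the Actb 3′ minus 5′ difference (1.28), the Gapdh 3′ minus 5′ difference (0.84), Calcrl (9.25) and S1pr1 (10.99). LSEC_0h array 17 stood apart in Akr1b8 (8.44), Scn7a (6.11), Selp (6.36) and St3gal2 (8.91). LSEC_2h array 6 stood apart in cholangiocyte and other epithelial markers (6.61), Cyp51 (8.5) and Mfap4 (6.93). LSEC_2h array 7 stood apart in Apln (6.55), Cxcl1 (13.09), Klrd1 (7.49), Laptm5 (8.34) and Ly6c (8.1). LSEC_42h array 1 stood apart in cholangiocyte and other epithelial markers (6.22). LSEC_42h array 12 stood apart in RT1-Ba (6.23). LSEC_42h array 2 stood apart in Idi1 (10.94). LSEC_42h array 3 stood apart in Gja4 (7.46) and Gpx8 (10.11).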

How the results depend on the processing

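Leaving out sets of arrays and leaving out marker list members were tests chosen after the values per array were seen, as was the Actb measure of RNA quality. No named gene called in the main fit or in an alternative reversed its direction between them, but the majority direction over all genes did, as given below. Changes of sign with no call on either side were not counted. Of 471 results for named genes, 347 kept their side of the threshold in every alternative with no such reversal. The test against a 1.5-fold change ended the call of 120 of the 471 and quantile normalization that of 14.

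The test against a 1.5-fold change, a stricter question by construction, called 1088 genes between the organs, 1692 at 2 h, 1035 at 42 h and 1769 between 2 h and 42 h. With dim genes left out, 6803 genes were tested, and 5108 changed at 2 h and 4963 between 2 h and 42 h. The share of changed genes that rose at 2 h went from 55.9% to 36.1% with that filter and to 48.8% with quantile normalization, and between 2 h and 42 h from 46.0% to 64.8% and 53.2%. With the test against a 1.5-fold change the share higher went from 41.7% to 58.3% between the organs, 55.9% to 40.5% at 2 h, 58.8% to 49% at 42 h and 46% to 67.1% between 2 h and 42 h. Without the 2-fold minimum, which admits more genes by construction, 1342 genes higher in LSEC_0h fell by 42 h, 822 fell between 2 h and 42 h, and 671 genes higher in LMEC_0h rose by 42 h. With only the groups compared in each fit, 224 genes higher in LMEC_0h rose by 42 h; the cause was not tested. The number of lists called was 0 with an estimated correlation and 72 with fry, against 43, and with dim genes left out 8 list calls were lost and 5 gained.

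Leaving out each array in turn gave 4798 to 5086 genes between the organs, 7781 to 8145 at 2 h, 5050 to 5278 at 42 h and 7518 to 7825 between 2 h and 42 h. The overlaps were 355 to 379, 149 to 200 and 138 to 163, the lists called 40 to 44, and the Actb difference 0.81 to 0.90. The mean over the probe sets of a gene moved nothing, since each gene had 1, and a pseudocount did not apply to log2 values. Signal near background limits dim genes, which the filter leaves out.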

Other observations

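The interferon-stimulated list was chosen after its members were seen among the genes that changed most, so its values describe the arrays and test nothing. Of its 22 measured members, 16 rose at 2 h, 21 fell between 2 h and 42 h and 18 fell by 42 h against LSEC_0h. Its mean was 10.4 to 10.94 in the LSEC_2h arrays, 7.29 to 7.49 at 42 h, 8.05 to 9.65 in LSEC_0h and 8.5 to 9.66 in LMEC_0h.

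The bacterial BioB hybridisation controls averaged 8.72 at 2 h and 7.75 to 8.06 in the other groups. The 5S rRNA probe set averaged 9.61 ± 0.38 (SD, n = 4) at 2 h, 8.23 ± 1.01 (SD, n = 4) at 42 h, 7.69 ± 0.23 (SD, n = 5) in LSEC_0h and 7.14 ± 0.36 (SD, n = 5) in LMEC_0h.

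Other divisions of the arrays of 2 groups were run for the counts of changed genes, the counts of lists called and the overlaps of 370, 188 and 147 genes. Chance in the grouping of these arrays can be excluded for the genes changed between the organs (5235, highest other 29), at 42 h (5570, highest other 3990) and between 2 h and 42 h (7939, highest other 1270), each reached by 1 division, the real one. Chance between animals is not covered, as the labels do not state the animals. Chance cannot be excluded for the number of lists called: as many as the real 15, 10, 11 and 7 came from 23, 12 and 33 of 100 divisions and 26 of 35, with up to 19, 13, 14 and 12 lists in the others. Nor can it for the genes higher in LMEC_0h that rose by 42 h (147, highest other 240), with 5 of 100. That count asks for overlaps as large as the real one, so it decides nothing about an overlap below that of independent lists.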
